A study of Mus musculus with 29 samples.

How the data were processed

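RNA was sequenced from colon tissue of C57BL/6J mice in 2 experiments. In the first, mice drank plain water or water with dextran sulfate sodium (DSS, a polymer that injures the colon epithelium and is widely used to induce colitis) for 3 days, and the proximal and distal parts of the colon were taken. This gave 4 groups of 5 libraries, 20 in all. In the second, proximal colon was taken on day 1, on day 7 or on day 21, which gave 3 groups of 3 libraries, 9 in all. What the days are counted from is not given in the sources used here. Every library was placed in its group by its title in the labels. The labels do not say that the libraries of a group came from separate animals, so the p-values measure the spread between these samples, part of which may be technical. In the age series 8 of 9 libraries held transcripts of both sexes, so a library may be a pool of animals.

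Per the labels' protocols, total RNA was extracted with Trizol and standard Illumina libraries were made. Per the submitters' processing notes, reads were handled with cutadapt 1.9 and FastQC, and the genome build was mm10. The aligner, the counting program, its strand setting and the annotation release are not given in the sources used here. For the DSS experiment the authors deposited whole-number counts per Ensembl gene, without normalization. For the age series the authors deposited values already scaled for gene length and depth, taken here as FPKM (fragments scaled by gene length and library size) although the file does not name the unit. This was judged from the values themselves, which are fractional, sum to between 301131 and 380463 per library and fall with gene length at a given count in the other table. The counts table held 35896 genes and the other table held 40053 genes, of which 5812 were listed at 0 in every library. Gene symbols, identifiers and coordinates (GRCm38, which is mm10) came from the GENCODE vM21 annotation, matched by identifier for 35783 genes of the first table and by the authors' names for 38672 genes of the second.

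The total count per library of the DSS experiment lay between 54171392 and 65578794. In mega-counts (M), group means were 63.8 M for control distal, 61.2 M for control proximal, 57.6 M for DSS distal and 63.3 M for DSS proximal colon. For a gene at 0 the floor was 3 counts per library at the depth of the group at 0. Among low counts the values 4 and 8 were more frequent than their neighbours (20736 entries of 4 against 10600 of 3 and 6336 of 5), so 1 fragment may have been counted more than once, and intervals and floors cover counting error only. No pair of replicates agreed within sampling noise: the chi-square per gene between replicates of a group lay between 20.4 and 146. The FPKM table does not give depth. The most common ratio of low values between libraries put the depth of the 9 libraries at 0.622 to 1 relative to the first day 1 library, with weak peaks, and because the values include fractional estimates, read counts were not recovered.

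Counts were analysed with edgeR 4.0.16 in R 4.3.3: genes were kept with filterByExpr (21152 genes), scaled by TMM, and tested with the quasi-likelihood test in 1 fit of all 20 libraries with a mean for each of the 4 groups. The comparisons were DSS against water in each part of the colon, the difference between these effects (the interaction, distal minus proximal), and proximal against distal colon with water and with DSS. FPKM values were analysed with limma 3.58.1 (eBayes with trend) on log2(FPKM + 1), for genes of at least 1 FPKM in at least 3 libraries (15040 genes), in 1 fit of the 9 libraries. Fold changes of this table are therefore on the log2(FPKM + 1) scale, which understates the change of low genes. The tables were normalized separately, and no test was made between them. Genes with a Benjamini-Hochberg adjusted p under 0.05 were called changed. Every adjusted p of a gene in the DSS experiment is from edgeR, and every one in the age series from limma. Group values are the mean ± SD of TMM-normalized CPM (counts scaled by library size, n = 5) or of FPKM (n = 3), and log2 fold changes are given ± SE.

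Before the data were examined, 45 gene lists (pathways, cell types and tissue markers, 757 members) and the rule for named genes were fixed. The rule took, per comparison, the 8 genes with the largest rise and the 8 with the largest fall (5 and 5 in the interaction) among called genes whose groups do not overlap and whose higher group has a mean of at least 50 counts or 5 FPKM, without predicted genes and antigen receptor segments. It added 2 to 4 members of each described list by smallest adjusted p, and 12 genes of bile acid metabolism whatever their result. Lists with at least 4 measured members were tested with limma's camera at a preset correlation of 0.01 between genes, with Benjamini-Hochberg adjustment over the lists of a comparison, and again with the correlation estimated from the residuals. The camera p-values at the preset correlation rest on a small assumed correlation, so the value with an estimated correlation is given beside each. For each list the members called over all genes tested are counted, and the members called when adjusted over the list alone.

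The procedure was tested on simulated data based on the real libraries with 200 changed genes. For DSS in the distal colon it recovered 41.8% of genes changed 1.5-fold, 62.7% of those changed 2-fold and 80.3% of those changed 4-fold, with 3 unchanged genes among 126 calls. For day 21 against day 1 the shares were 56.7%, 95.5% and 100%, with 12 unchanged genes among 180 calls. Such false calls passed 5% in all 3 age comparisons, with 15 of 184 for day 7 against day 1, and were 20 of 149 with DESeq2 in distal colon. The alternatives were other scalings (DESeq2 size factors and upper quartile for counts, quantile and TMM-type for FPKM), other filters on low values, a pseudocount of 0.1, DESeq2 1.42.0, limma with array weights, a fit of the compared groups alone, the replicate number as a block, a minimum change of 1 on the log2 scale, and leaving out each library in turn. Reads shared between close relatives (the Ly6, Reg3, Ces1, Ces2, Ugt and Cyp families, the Rn7s genes, Hnrnpa3 and mitochondrial genes with nuclear copies) or between overlapping genes could not in general be told apart from these tables, so values of such genes are uncertain. Results of 4 genes named by the rule are not reported here. Figures were drawn with matplotlib 3.10.9.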

Results

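Gene expression was measured by RNA sequencing in whole colon tissue of C57BL/6J mice. The series asks how bile acid metabolism changes during development and under inflammatory challenge. In the DSS experiment, 5 libraries each came from the proximal and the distal colon of mice that drank water, and 5 each from those parts after 3 days of DSS. The age series held 3 libraries of proximal colon for each of day 1, day 7 and day 21. Libraries of the DSS experiment held 54171392 to 65578794 counts, and the share of counts on mitochondrial genes was 5.11% to 9.54%. In the age series, for which depth is unknown, mitochondrial genes took 19.7% to 29.4% of the FPKM sum, with the highest share in day 1 library 1.

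Genes that handle bile acids differed between the colon parts of mice on water. Slc10a2 encodes the apical transporter that takes bile acids up into the epithelium (ENSMUSG00000023073, chromosome 8, 5083219 to 5105351, minus strand). It reached 349.8 ± 58.7 CPM in proximal and 9.74 ± 3.61 CPM in distal colon of mice on water (log2 fold change 5.17 ± 0.23, adjusted p = 1.26e-13). Slc51a and Slc51b form the basolateral exporter. Slc51a (ENSMUSG00000035699, chromosome 16, 32474504 to 32487879, minus strand) was at 102 ± 12.9 against 0.157 ± 0.0783 CPM (adjusted p = 7.85e-16). Slc51b was at 45.5 ± 10.7 against 7.56 ± 1.5 CPM, a log2 fold change of 2.59 ± 0.19 (adjusted p = 3.92e-10). Nr1h4, the nuclear bile acid receptor FXR (ENSMUSG00000047638, chromosome 10, 89454234 to 89533585, minus strand), was higher proximally by 1.30 ± 0.13 on the log2 scale (adjusted p = 5.44e-08). The basolateral exporter Abcc3 was higher by 0.96 ± 0.11 (adjusted p = 2.01e-07). Of the 15 measured bile acid transport genes 8 were higher and 1 was lower proximally, the same numbers when adjusted over the list alone (camera adjusted p = 7.47e-08, adjusted p = 0.00323 with an estimated correlation).

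Bile acid receptors and their targets went both ways, with 5 of 15 higher and 4 lower proximally (5 and 5 over the list alone). Camera did not call the list (adjusted p = 0.630), its median was -0.11 and its mean 0.90. Cyp3a25, a detoxifying cytochrome, had no count in any distal library and was at least 105-fold higher proximally (4.92 ± 1.10 CPM). Klb, the co-receptor for endocrine fibroblast growth factors, was lower proximally (-2.28 ± 0.19, adjusted p = 2.22e-09), as was the oxysterol receptor Nr1h3 (-0.88 ± 0.09, adjusted p = 1.36e-07). Vdr, the vitamin D receptor that also binds lithocholic acid, was at 356 ± 48.7 against 384 ± 78.2 CPM (adjusted p = 0.610). Nr1i2 was at 73.8 ± 7.81 against 78.4 ± 2.98 CPM (adjusted p = 0.452) and Cyp27a1, an enzyme of the alternative synthesis pathway, at 57.8 ± 6.83 against 58.7 ± 5.87 CPM (adjusted p = 0.921). The membrane receptor gene Gpbar1 was at 0.552 ± 0.332 against 1.02 ± 0.157 CPM (adjusted p = 0.0678). Fabp6, the ileal bile acid binding protein, was low in both parts (1.29 ± 0.189 against 1.62 ± 0.571 CPM, adjusted p = 0.723). Fgf15, the FXR target that signals to the liver, stayed under the expression filter, with at most 0.483 CPM in any of the 20 libraries. Cyp7a1, the rate-limiting enzyme of bile acid synthesis, was not analysed in this experiment.

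Other programs parted along the colon as well. Among 24 measured patterning factors 12 were higher and 9 lower proximally. Hoxb6 (83.2 ± 10.6 CPM proximal, 1.73 ± 0.194 CPM distal) and the homeobox factor Isx (161 ± 18.2 against 1.43 ± 0.158 CPM) marked the proximal part, and Hoxb13 (0.0551 ± 0.0911 against 421 ± 29.1 CPM) and Hoxd13 (0.213 ± 0.0912 against 223 ± 23.9 CPM) the distal part. The counts were the same over the list alone, and this list with members for both ends was not called as a whole (camera adjusted p = 0.125, adjusted p = 0.358 with an estimated correlation). Of 30 conjugation and detoxification genes 21 were higher and 3 lower proximally (21 and 4 over the list alone), led by Cyp2c65 (6.07 ± 0.18, adjusted p = 2.80e-16) and the retinaldehyde dehydrogenase Aldh1a1 (3.56 ± 0.13, adjusted p = 3.41e-15). The list had camera adjusted p = 7.63e-27, adjusted p = 0.00304 with an estimated correlation. Of 20 genes of fatty acid oxidation and PPAR targets 13 were higher and 1 lower (14 and 1 over the list alone), among them Fabp2 (387 ± 107 against 8.89 ± 2.83 CPM). The call of the list was lost (adjusted p = 0.0842 with an estimated correlation).

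Secretory and sensory cell markers were higher proximally. They included 12 of 16 enteroendocrine genes, with 2 lower (13 and 2 over the list alone), with camera adjusted p = 7.23e-10, adjusted p = 0.00575 with an estimated correlation. Among these were the hormone genes Sct (4.29 ± 0.20, adjusted p = 2.18e-13) and Nts (47.4 ± 11.7 against 0.0623 ± 0.0876 CPM). For tuft cells the count was 10 of 14 with 1 lower, as over the list alone, with camera adjusted p = 1.88e-06, adjusted p = 0.00575 with an estimated correlation. Among them was Trpm5 (2.15 ± 0.18, adjusted p = 3.06e-09). For goblet cells 11 of 18 were higher and 4 lower, as over the list alone. They included Muc2, the main gel-forming mucin, at 14077 ± 3432 against 1255 ± 227 CPM, and the list had camera adjusted p = 4.15e-07, adjusted p = 0.0501 with an estimated correlation. Of 17 genes typical of the suckling enterocyte 8 were higher and 2 lower proximally, as over the list alone, with camera adjusted p = 0.00214, adjusted p = 0.0411 with an estimated correlation. These included the endocytic receptor genes Cubn (4.04 ± 0.24, adjusted p = 1.28e-11) and Amn (4.45 ± 0.36, adjusted p = 1.84e-09). Of 19 T cell genes 12 were higher and none lower, as over the list alone, such as Gzmb (6.59 ± 0.760 against 0.428 ± 0.160 CPM; camera adjusted p = 0.00246, adjusted p = 0.486 with an estimated correlation).

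The distal colon carried the other side of the split. All 13 measured B cell genes were lower proximally, with camera adjusted p = 1.07e-06, adjusted p = 0.237 with an estimated correlation. Cd22 (-2.71 ± 0.33, adjusted p = 9.97e-07) was among them. So were 16 of 18 fibroblast and matrix genes, such as Fn1 (-1.65 ± 0.11, adjusted p = 7.61e-11), with camera adjusted p = 1.07e-06, adjusted p = 0.111 with an estimated correlation. Smooth muscle genes were lower proximally in 11 of 13 cases, such as Des (-1.45 ± 0.15, adjusted p = 1.16e-07), with camera adjusted p = 5.90e-07, adjusted p = 0.180 with an estimated correlation. These 3 counts were the same adjusted over their lists alone. Of 21 ion and water transport genes 4 were higher and 9 lower (4 and 10 over the list alone). The proton pump Atp12a was at 3.86 ± 1.54 against 481 ± 151 CPM, the water channel Aqp8 at 17.8 ± 6.83 against 545 ± 32.5 CPM and the chloride exchanger Slc26a3 at 247 ± 49.8 against 1253 ± 132 CPM (camera adjusted p = 8.66e-04, adjusted p = 0.117 with an estimated correlation). Of 6 measured hepatocyte genes 3 were lower proximally, as over the list alone, with camera adjusted p = 0.00530, adjusted p = 0.0411 with an estimated correlation. Among them was Ttr (2.33 ± 0.380 against 42.4 ± 3.37 CPM), which is also known from endocrine cells. Of 15 circadian clock genes 7 were lower proximally and none higher (7 and 1 over the list alone), with adjusted p = 0.553 with an estimated correlation. These included Arntl (-2.29 ± 0.19, adjusted p = 2.92e-09).

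The largest differences were close to all or nothing. Reg3b, an antibacterial lectin, was at 554 ± 184 CPM proximally and 0.00610 ± 0.0136 CPM distally, and Reg3g at 119 ± 49.2 and 0.0441 ± 0.0438 CPM. Abca12 was at 64.6 ± 4.84 and 0.0123 ± 0.0274 CPM. Ugt2b5 was at least 1028-fold higher proximally, ccdc198 at least 331-fold, Cyp3a44 at least 166-fold and Defb37 at least 114-fold, each against 0 counts in all 5 distal libraries. In the other direction Evx2 was at least 223-fold lower proximally, Vtcn1 at least 100.1-fold, Defb45 at least 97.6-fold and Klk15 at least 70.8-fold. Ly6g was at 0.0274 ± 0.0399 against 182 ± 27.8 CPM, Casp14 at 0.0130 ± 0.0292 against 38.7 ± 6.86 CPM and the noncoding RNA Hottip at 0.0228 ± 0.0358 against 34.8 ± 5.69 CPM. In all, 3069 genes were higher and 3418 lower proximally with water, against 3253 and 3152 with DESeq2 size factors.

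With DSS the colon parts stayed apart: 3803 genes were higher and 3451 lower in proximal colon. Slc51a was at 97.2 ± 10.7 against 0.0905 ± 0.123 CPM and Slc10a2 at 298 ± 16.8 against 30.3 ± 7.70 CPM, and of the 15 bile acid transport genes 8 were higher and 3 lower, as over the list alone (camera adjusted p = 1.87e-05, adjusted p = 0.0160 with an estimated correlation). Gpbar1 (-1.68 ± 0.37, adjusted p = 9.61e-04), Cyp27a1 (-0.72 ± 0.12, adjusted p = 7.67e-05) and Nr1i2 (-0.26 ± 0.08, adjusted p = 0.0130) were lower proximally. Of the 29 cell cycle genes 28 were higher proximally with DSS, as over the list alone, with camera adjusted p = 4.56e-12, adjusted p = 0.239 with an estimated correlation. The DNA replication gene Mcm5 (31.2 ± 8.87 against 7.34 ± 1.14 CPM) was among them. At the extremes, Abca12 was at least 1568-fold and Cyp2c66 at least 212-fold higher proximally, and Hoxb13 at least 8802-fold and Casp14 at least 881-fold lower. Fabp6 was called higher (1.85 ± 0.57, adjusted p = 0.0144), which rested on DSS proximal library 5: without it the adjusted p was 0.416.

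**Figure D1:**
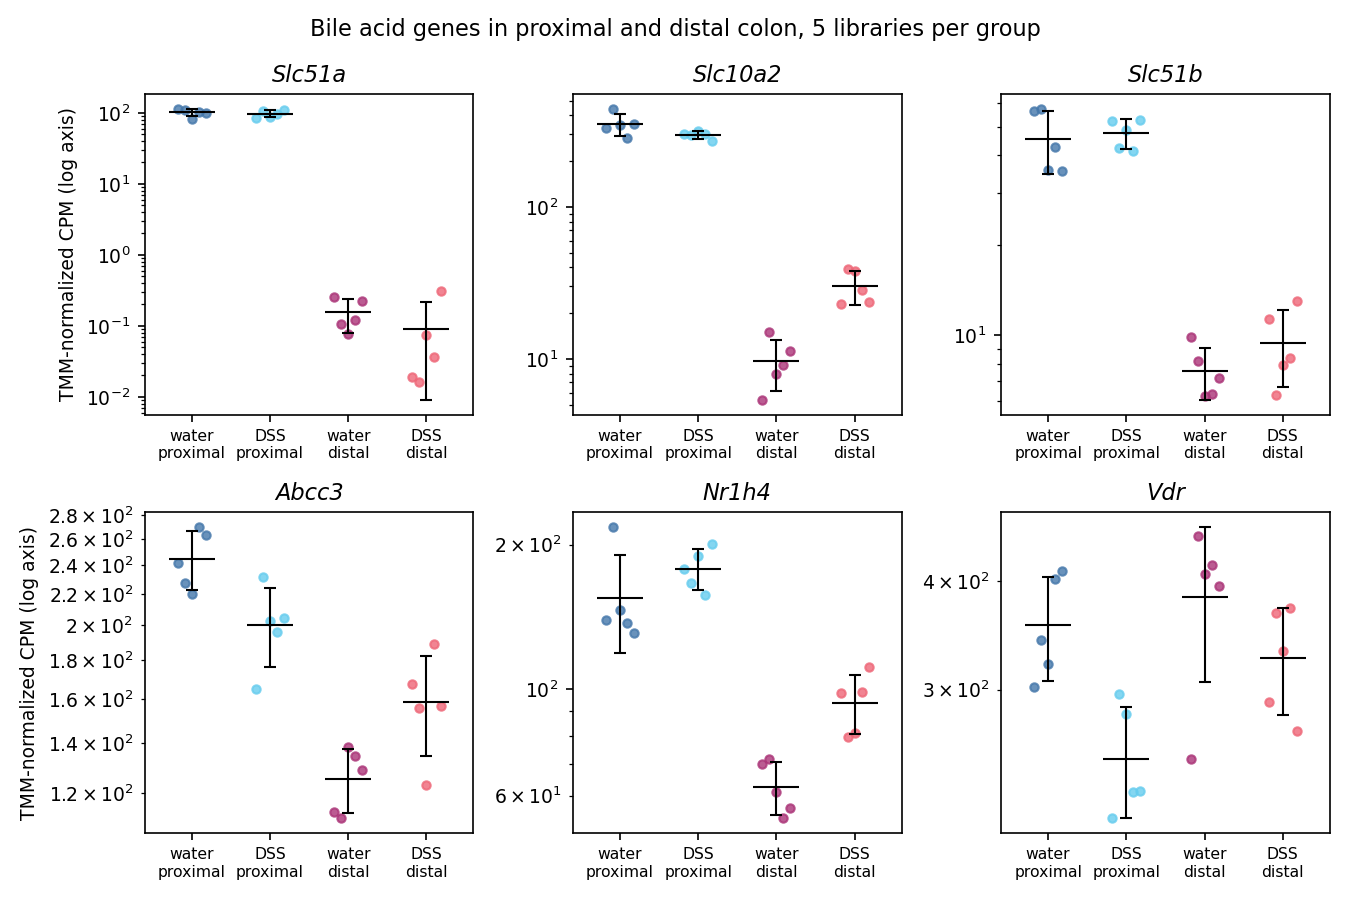
TMM-normalized CPM (log axis) of 6 bile acid genes in proximal and distal colon with water or DSS: points are the 5 libraries of a group, the horizontal mark their mean and the bars the SD, with the lower bar of Slc51a in DSS distal colon shortened because the SD exceeds the mean. Slc51a lay near 100 CPM in proximal and under 0.31 CPM in distal colon, and Slc10a2 rose in distal colon from 9.74 to 30.3 CPM with DSS.

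In the distal colon, 3 days of DSS lowered the genes of crypt stem cells and of dividing cells. Lgr5, the receptor that marks crypt stem cells (ENSMUSG00000020140, chromosome 10, 115450311 to 115587780, minus strand), fell from 13 ± 1.20 to 0.469 ± 0.195 CPM (log2 fold change -4.79 ± 0.32, adjusted p = 6.28e-09). Ascl2, the stem cell transcription factor (ENSMUSG00000009248, chromosome 7, 142966829 to 142969264, minus strand), fell from 9.92 ± 1.61 to 0.0832 ± 0.106 CPM (-6.81 ± 0.51, adjusted p = 2.38e-08), and the Wnt target Axin2 from 24.7 ± 3.70 to 3.87 ± 0.822 CPM (adjusted p = 6.28e-09). Of 16 measured stem cell and Wnt genes 9 fell and none rose (10 over the list alone), with camera adjusted p = 2.32e-30, adjusted p = 2.04e-05 with an estimated correlation. Of 29 cell cycle genes 26 fell and none rose (27 over the list alone). Among them Mki67 went from 124 ± 16.2 to 42.7 ± 12 CPM, Aurkb changed by -1.77 ± 0.18 (adjusted p = 2.31e-06), and the replication gene Mcm5 by -1.51 ± 0.17 (adjusted p = 5.58e-06). The list had camera adjusted p = 1.56e-45, adjusted p = 0.0263 with an estimated correlation.

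Genes of the crypt base, of ion secretion and of differentiated cells moved in both directions. Cldn2, a pore-forming claudin, fell from 163 ± 8.02 to 19.9 ± 10.5 CPM (-3.04 ± 0.28, adjusted p = 5.16e-07) and Cldn15 by -1.04 ± 0.11 (adjusted p = 2.37e-06), while the barrier claudin Cldn8 rose (0.92 ± 0.15, adjusted p = 3.19e-04). No other of the 18 tight junction genes was called, and the list as a whole was not (camera adjusted p = 0.847); its median was 0.07 and its mean -0.13. Of 21 ion and water transport genes 7 fell and 1 rose (8 and 5 over the list alone), with adjusted p = 0.339 with an estimated correlation. The chloride channel Cftr (-1.14 ± 0.13, adjusted p = 4.32e-06) and the cotransporter Slc12a2 (-0.80 ± 0.09, adjusted p = 3.98e-06) fell, and Clca4b rose (58.6 ± 54.9 against 3.34 ± 1.58 CPM, adjusted p = 1.94e-04). Of 16 enteroendocrine genes 6 rose and 1 fell, as over the list alone: the hormone genes Gcg (1.07 ± 0.13) and Pyy (0.92 ± 0.13, adjusted p = 5.27e-05) rose. Neurog3, the factor of endocrine progenitors, was at 0.0370 ± 0.0519 against 1.02 ± 0.298 CPM (adjusted p = 1.12e-04). The list had camera adjusted p = 1.81e-05, adjusted p = 0.0673 with an estimated correlation. Of 18 goblet cell genes 5 rose and none fell (9 and 1 over the list alone), with adjusted p = 0.250 with an estimated correlation. Among them was Muc2 (2026 ± 309.6 against 1255 ± 227 CPM, adjusted p = 0.00879). Of 22 colonocyte genes 2 rose and 6 fell, as over the list alone, with Car1, a carbonic anhydrase, up (2176 ± 283 against 1309 ± 112 CPM, adjusted p = 1.21e-04) and the water channel Aqp8 down (284 ± 68.1 against 545 ± 32.5 CPM, adjusted p = 0.0104). Camera did not call this list (adjusted p = 0.671).

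Macrophage genes rose in distal colon, and other immune genes went both ways. Of 19 monocyte and macrophage genes 13 rose and none fell (13 and 1 over the list alone), with camera adjusted p = 6.66e-12, adjusted p = 0.0486 with an estimated correlation. These included Cd68 (24.5 ± 4.84 against 9.88 ± 1.05 CPM, adjusted p = 4.84e-06) and Ms4a7 (17.1 ± 2.41 against 7.14 ± 1.49 CPM, adjusted p = 1.79e-06). Of 32 interferon response genes 11 rose (22 over the list alone), with adjusted p = 0.246 with an estimated correlation. The nucleic acid sensor Zbp1 (1.39 ± 0.21, adjusted p = 1.39e-04) and Isg15 (1.11 ± 0.27, adjusted p = 0.0105) were among them. Of 21 cytokine and chemokine genes 7 rose, as over the list alone, with adjusted p = 0.250 with an estimated correlation. Among them were Ccl8 (11.2 ± 4.43 against 1.55 ± 0.628 CPM, adjusted p = 7.02e-06) and Il1rn, which encodes the interleukin 1 receptor antagonist (0.57 ± 0.10, adjusted p = 6.58e-04). Of 23 antimicrobial and acute phase genes 6 rose and 2 fell, as over the list alone, with adjusted p = 0.424 with an estimated correlation. The protease inhibitor Slpi rose (2.44 ± 0.40, adjusted p = 3.62e-04) and the superoxide-generating oxidase Nox1 fell (-2.68 ± 0.43, adjusted p = 2.81e-04). Of 17 regenerative epithelium genes 6 rose, as over the list alone, with adjusted p = 0.176 with an estimated correlation. These included Ly6a (435 ± 123 against 174 ± 33.3 CPM, adjusted p = 1.42e-04). B cell genes had a median of -0.95 with 2 of 13 called lower, Bank1 (adjusted p = 0.00766) and Blk (5 over the list alone; adjusted p = 0.339 with an estimated correlation). The call of Blk was lost without control library 1 or 2 or DSS library 4 or 5, with adjusted p up to 0.0696. Of 13 smooth muscle genes 6 rose and 1 fell (10 and 1 over the list alone), with adjusted p = 0.339 with an estimated correlation. Actg2 rose (0.88 ± 0.15, adjusted p = 4.37e-04) and the hedgehog-binding Hhip fell (-1.73 ± 0.20, adjusted p = 7.60e-06).

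For bile acids, Slc10a2 rose in distal colon from 9.74 ± 3.61 to 30.3 ± 7.70 CPM (1.64 ± 0.20, adjusted p = 1.68e-05), and the homeobox gene Isx from 1.43 ± 0.158 to 8.74 ± 4.15 CPM (2.61 ± 0.22, adjusted p = 1.77e-07; chromosome 8, 74873173 to 74893506, plus strand). Nr1h4 rose from 62.6 ± 7.93 to 93.8 ± 13.2 CPM (0.58 ± 0.13, adjusted p = 0.00545). Slc51b was at 9.39 ± 2.71 against 7.56 ± 1.5 CPM (adjusted p = 0.339) and Vdr at 326 ± 46.0 against 384 ± 78.2 CPM (adjusted p = 0.345). Cyp27a1 was at 72.6 ± 9.79 against 58.7 ± 5.87 CPM (adjusted p = 0.129) and Nr1i2 at 83.0 ± 7.02 against 78.4 ± 2.98 CPM (adjusted p = 0.610). Low values were those of Gpbar1 (1.52 ± 0.372 against 1.02 ± 0.157 CPM, adjusted p = 0.364), Fabp6 (1.25 ± 0.479 against 1.62 ± 0.571 CPM, adjusted p = 0.769) and Slc51a (0.0905 ± 0.123 against 0.157 ± 0.0783 CPM, adjusted p = 0.473). Abcc3 (0.34 ± 0.10, adjusted p = 0.0452) and Nr1h3 (-0.32 ± 0.09, adjusted p = 0.0335) passed the threshold narrowly. The call of Abcc3 ended without control library 1, 2 or 5 or DSS library 1, 2, 4 or 5, and that of Nr1h3 without control or DSS library 1, 4 or 5 (adjusted p up to 0.133 and 0.108). Of 15 bile acid transport genes 2 rose (2 and 1 lower over the list alone), and of 15 receptor and target genes 1 rose and 1 fell, as over the list alone. Camera called neither list (adjusted p = 0.322 and 0.770). Of 30 conjugation and detoxification genes 3 rose and 5 fell (6 and 9 over the list alone), the glutathione transferases Gsta3 (-1.81 ± 0.17, adjusted p = 5.47e-07) and Gstm1 (-0.67 ± 0.10, adjusted p = 1.68e-04) among those that fell (adjusted p = 0.473 with an estimated correlation).

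In all, 794 genes rose and 1169 fell with DSS in distal colon, against 935 and 1008 with DESeq2 size factors and 1327 and 1334 with DESeq2. The inducible nitric oxide synthase gene Nos2 rose by 2.32 ± 0.58 (adjusted p = 0.0127) and BB123696 by 2.49 ± 0.37 (adjusted p = 1.54e-04). Cd207, a Langerhans-type dendritic cell marker, changed by -3.44 ± 0.65 (adjusted p = 0.00469) and Xkr5 by -2.88 ± 0.48 (adjusted p = 4.18e-04). Ces1b was at 0.0323 ± 0.0723 against 1.09 ± 0.239 CPM. Its call was lost with DESeq2 (adjusted p = 0.125). The calls of Btn1a1 (2.25 ± 0.57) and Vwa2 (-2.93 ± 0.75) ended when the 10 distal libraries were fitted alone (adjusted p = 0.0510 and 0.0605). The call of Pcdhgb1 (2.19 ± 0.58) was lost without control library 1 or DSS library 1 (adjusted p up to 0.0795).

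In the proximal colon DSS raised inflammatory genes, with no called change in any cell cycle gene. Il1rn rose from 20.1 ± 2.32 to 51.7 ± 9.34 CPM (log2 fold change 1.36 ± 0.10, adjusted p = 2.29e-07), and the monocyte chemokine Ccl2 from 0.896 ± 0.249 to 5.71 ± 4.11 CPM (2.67 ± 0.40, adjusted p = 2.90e-04). The neutrophil chemokine Cxcl5 rose from 0.0898 ± 0.0855 to 3.38 ± 3.23 CPM (5.19 ± 0.68, adjusted p = 9.54e-05). The matrix proteases Mmp3 (26.8 ± 21.1 against 0.604 ± 0.224 CPM, adjusted p = 8.27e-06) and Mmp10 (9.58 ± 7.36 against 0.147 ± 0.198 CPM, adjusted p = 6.76e-05) rose too. Acod1, the itaconate-producing enzyme of activated macrophages, had no count in the 5 control libraries and was at least 27.4-fold higher (1.35 ± 1.28 CPM). Of 21 cytokine and chemokine genes 10 rose and none fell (13 over the list alone), with camera adjusted p = 6.65e-21, adjusted p = 0.0143 with an estimated correlation. The epithelial gene Clca4b rose from 2.66 ± 0.842 to 56.5 ± 43.0 CPM (adjusted p = 2.57e-04).

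Markers of myeloid and stromal cells rose with them. Of 16 neutrophil genes 6 rose and none fell (12 over the list alone), with camera adjusted p = 6.85e-13, adjusted p = 0.0143 with an estimated correlation. Csf3r, the receptor for granulocyte growth factor (1.48 ± 0.27, adjusted p = 0.00176), and Itgam (0.90 ± 0.19, adjusted p = 0.00774) rose. Ly6g, also on this list (chromosome 15, 75155240 to 75159126, plus strand), was at 9.68 ± 6.22 against 0.0274 ± 0.0399 CPM (adjusted p = 9.66e-07), while the neutrophil transcripts S100a8 and S100a9 were at most 2.44 and 4.33 CPM in these libraries, and distal colon on water held 182 ± 27.8 CPM of Ly6g. Of 19 monocyte and macrophage genes 11 rose (13 over the list alone), with camera adjusted p = 2.63e-15, adjusted p = 0.0143 with an estimated correlation. Among them were Cd68 (12.6 ± 2.28 against 5.48 ± 0.781 CPM, adjusted p = 4.28e-05) and the high-affinity antibody receptor Fcgr1 (1.29 ± 0.19, adjusted p = 2.49e-04). Of 18 fibroblast and matrix genes 8 rose (10 and 1 lower over the list alone), with camera adjusted p = 3.12e-11, adjusted p = 0.0323 with an estimated correlation. These included the BMP antagonist Grem1 (118 ± 39.2 against 32.1 ± 4.96 CPM, adjusted p = 9.76e-06) and the Wnt amplifier Rspo3 (0.90 ± 0.15, adjusted p = 9.02e-04). Of 17 regenerative epithelium genes 6 rose (11 over the list alone), with camera adjusted p = 1.19e-10, adjusted p = 0.0177 with an estimated correlation. Ly6a (244 ± 72.3 against 75.5 ± 12.1 CPM, adjusted p = 2.73e-05) and Anxa3 (0.71 ± 0.08, adjusted p = 1.98e-05) were among them.

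Members of 6 further lists were called in proximal colon, none of them called as a list with an estimated correlation. Of 23 antimicrobial and acute phase genes 9 rose (11 and 1 lower over the list alone). Reg3b went from 554 ± 184 to 3165 ± 2409.9 CPM (adjusted p = 0.00156), Reg3g from 119 ± 49.2 to 721 ± 586 CPM (adjusted p = 0.00188), and Duoxa2, needed for hydrogen peroxide production, from 5.77 ± 1.28 to 25.4 ± 14.2 CPM (adjusted p = 0.00191; adjusted p = 0.217 with an estimated correlation). Of 32 interferon response genes 12 rose and 1 fell (15 and 2 over the list alone), with adjusted p = 0.217 with an estimated correlation. Among them were Cxcl10 (1.99 ± 0.36, adjusted p = 0.00186) and Gbp2 (1.59 ± 0.31, adjusted p = 0.00364). Of 16 ER stress genes 9 rose, as over the list alone, with camera adjusted p = 4.43e-08, adjusted p = 0.0617 with an estimated correlation. These included the chaperone Hspa5 (417 ± 34.6 against 259 ± 39.7 CPM, adjusted p = 0.00103). Of 25 cholesterol synthesis genes 10 rose (14 over the list alone), with adjusted p = 0.217 with an estimated correlation. Sqle (0.70 ± 0.15, adjusted p = 0.00696) and Hmgcs1 (0.67 ± 0.15, adjusted p = 0.0115) were among them. Of 15 clock genes 1 rose and 3 fell (1 and 8 over the list alone), with adjusted p = 0.217 with an estimated correlation. Arntl rose (1.17 ± 0.19, adjusted p = 5.76e-04) and the output gene Dbp fell (-0.75 ± 0.09, adjusted p = 2.73e-05). Time of day was not separated from DSS. The call of Tef ended without control library 5 or DSS library 1 or 5 (adjusted p up to 0.0624). That of Ciart ended without any 1 library except control 1 and DSS 3 (up to 0.161). Of 6 erythroid genes 4 fell, as over the list alone, with adjusted p = 0.190 with an estimated correlation. Among them was Hba-a1 (-1.07 ± 0.24, adjusted p = 0.0121). The calls of the other 3, Hba-a2, Hbb-bt and Hbb-bs, all ended without control library 1 or 3 or DSS library 1, 2, 4 or 5 (adjusted p up to 0.0997, 0.106 and 0.146).

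Slc10a2, Slc51a, Slc51b and Abcc3 did not change detectably in proximal colon. Slc10a2 was at 298 ± 16.8 against 349.8 ± 58.7 CPM (adjusted p = 0.620) and Slc51a at 97.2 ± 10.7 against 102 ± 12.9 CPM (adjusted p = 0.928). Slc51b was at 47.4 ± 5.43 against 45.5 ± 10.7 CPM (adjusted p = 0.933) and Abcc3 at 200.1 ± 23.9 against 245 ± 21.7 CPM (adjusted p = 0.122). Among receptors, Nr1h4 was at 178 ± 17.3 against 155 ± 35.8 CPM (adjusted p = 0.451), Nr1i2 at 69.2 ± 6.18 against 73.8 ± 7.81 CPM (adjusted p = 0.636) and Gpbar1 at 0.473 ± 0.166 against 0.552 ± 0.332 CPM (adjusted p = 0.859). Cyp27a1 was at 44.1 ± 8.95 against 57.8 ± 6.83 CPM (adjusted p = 0.0686). Fabp6 was at 4.50 ± 6.52 against 1.29 ± 0.189 CPM (adjusted p = 0.0703), with 16.1 CPM in DSS library 5. Among 15 transport genes the export pump Abcc2 fell (-0.71 ± 0.16, adjusted p = 0.0105) while none rose (2 higher and 4 lower over the list alone; camera adjusted p = 0.237). Of 15 receptor and target genes 5 fell and none rose (6 and 1 over the list alone; camera adjusted p = 0.0452, adjusted p = 0.217 with an estimated correlation). Klb (-0.85 ± 0.19), Nr1h3 (-0.39 ± 0.09) and Vdr (249.6 ± 36.5 against 356 ± 48.7 CPM, adjusted p = 0.0343) were among these 5. Without DSS library 1 the calls of Nr1h3 and Vdr ended, that of Vdr also without control library 2, 4 or 5 or DSS library 4 or 5 (adjusted p up to 0.114), and that of Klb when the 10 proximal libraries were fitted alone (adjusted p = 0.0784). Of 14 bile acid synthesis genes 1 rose and 2 fell (1 and 4 over the list alone; camera adjusted p = 0.304). The oxysterol hydroxylase Cyp7b1 rose by 0.80 ± 0.19 (adjusted p = 0.0149, and 0.0567 without DSS library 1). The calls of Baat (-2.12 ± 0.58) and Cyp39a1 (-0.46 ± 0.13) were lost without control library 2, 3 or 4 or DSS library 2 or 4, and without control library 1, 3, 4 or 5 or DSS library 1, 2 or 3, at adjusted p up to 0.133 and 0.136. Of 30 conjugation and detoxification genes 4 fell and 1 rose (7 and 1 over the list alone), with adjusted p = 0.217 with an estimated correlation. These included Aldh1a1 (-0.55 ± 0.11, adjusted p = 0.00610).

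In all, 704 genes rose and 432 fell in proximal colon. Serpina3m rose by 3.68 ± 0.74 (adjusted p = 0.00449). The largest falls included those of Serpina9 (-2.02 ± 0.30), Prr18 (-1.56 ± 0.33), the type 2 immunity gene Retnla (-1.46 ± 0.33), the cytochrome Cyp4b1 (-1.34 ± 0.22) and Odf3b (-1.30 ± 0.23). The call of Afm (-1.41 ± 0.34) ended without DSS library 1 (adjusted p = 0.0562). Those of Chil3, Pld5 and Cyp2w1 ended without any 1 of the proximal libraries (except control library 2 and DSS libraries 3 and 5 for Chil3, and DSS library 4 for Pld5), at adjusted p up to 0.112, 0.109 and 0.144. The number of genes called fell to 623 without DSS library 1 and to 740 and 724 without control libraries 4 and 5.

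The interaction compared the DSS effects of both parts. Crypt genes moved lower distally. The log2 difference was -4.42 ± 0.40 for Lgr5 (adjusted p = 3.25e-06) and -2.16 ± 0.18 for the Myc target Cdca7 (adjusted p = 1.11e-06). Of 16 stem cell and Wnt genes 8 moved lower distally and 1 higher (9 and 1 over the list alone), with camera adjusted p = 5.46e-22, adjusted p = 1.79e-04 with an estimated correlation. Proximally 2 of these 16 fell (Axin2 and Tnfrsf19) and 1 rose (Myc). Of 29 cell cycle genes 23 moved lower distally and none higher (28 over the list alone), with camera adjusted p = 1.02e-39, adjusted p = 0.0475 with an estimated correlation. Mcm5 (-1.80 ± 0.24, adjusted p = 1.44e-04) and Aurkb (-1.79 ± 0.25, adjusted p = 3.40e-04) were among them. Slc10a2 moved higher distally by 1.87 ± 0.28 (adjusted p = 5.66e-04), Isx by 2.74 ± 0.29 (adjusted p = 1.61e-05) and Abcc3 by 0.63 ± 0.15 (adjusted p = 0.0185). Cyp27a1 moved higher by 0.70 ± 0.17 (adjusted p = 0.0257, and 0.0512 without DSS proximal library 5). The difference was 0.38 ± 0.18 for Nr1h4 (adjusted p = 0.305), 0.28 ± 0.20 for Vdr (adjusted p = 0.538) and 0.25 ± 0.25 for Slc51b (adjusted p = 0.690).

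Of 21 cytokine and chemokine genes 5 moved lower distally and none higher (6 over the list alone), with adjusted p = 0.312 with an estimated correlation. Among them were Il1rn (-0.79 ± 0.14, adjusted p = 0.00267) and Il11 (-3.67 ± 0.72, adjusted p = 0.00553). The other 3 calls were lost with 1 library left out: Il33 without control proximal library 4, Cxcl5 without that library, control distal library 4 or DSS proximal library 1, and Il6 in 12 of 20 fits (adjusted p up to 0.0547 for Il33 and 0.258 for Il6). Of 16 enteroendocrine genes 5 moved higher distally and 1 lower (7 and 1 over the list alone), with camera adjusted p = 6.00e-06, adjusted p = 0.0600 with an estimated correlation. These included Gcg (1.02 ± 0.18) and Pyy (0.97 ± 0.18, adjusted p = 0.00337). Of 21 ion and water transport genes 4 moved lower and 1 higher (5 and 4 over the list alone; camera adjusted p = 0.0880), Cftr by -1.05 ± 0.18 (adjusted p = 0.00170) and Slc12a2 by -0.73 ± 0.12 (adjusted p = 0.00170). Of 13 B cell genes 1 moved, Bank1 (-1.52 ± 0.33, adjusted p = 0.0109), with 5 lower over the list alone (adjusted p = 0.288 with an estimated correlation). In all, 225 genes moved higher and 501 lower distally. With DESeq2 these numbers were 582 and 731. Both DSS effects pointed the same way for 209 genes that rose in both parts, against 26.4 in independent lists of these sizes, and for 85 that fell in both, against 23.9. In addition, 31 genes were called in opposite directions.

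**Figure D2:**
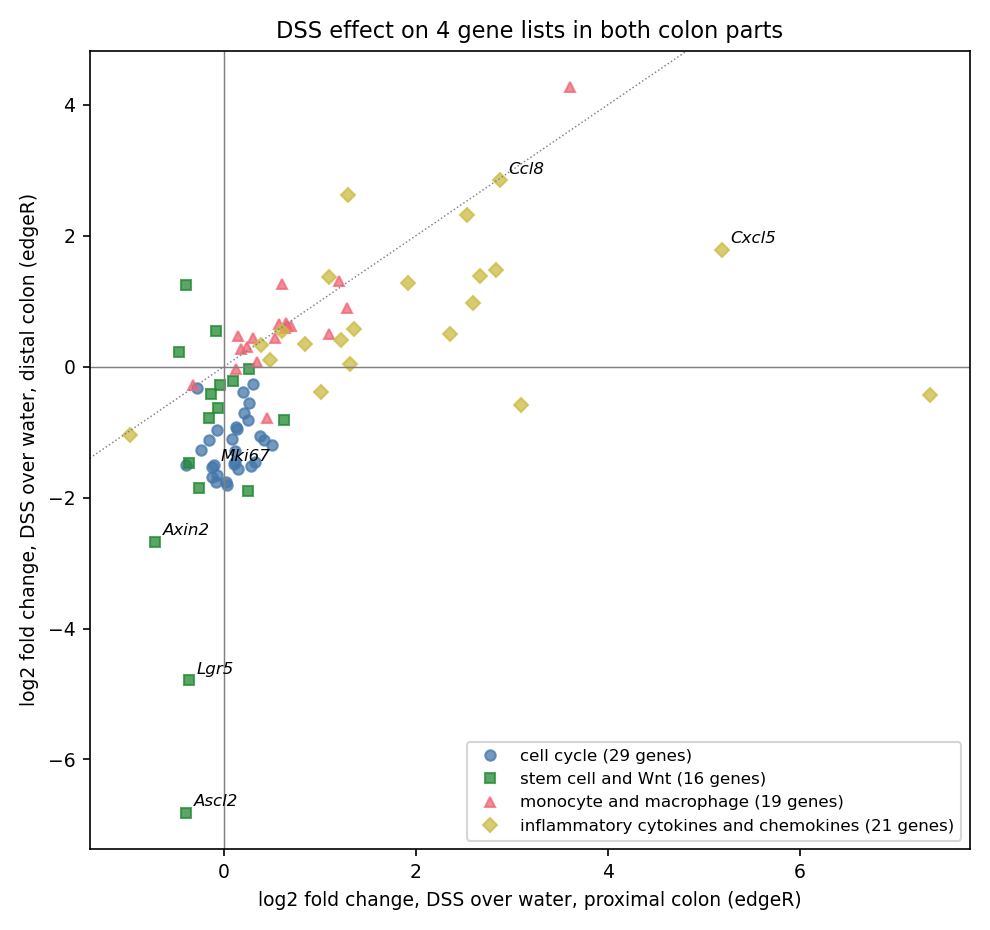
Log2 fold change (edgeR) of DSS over water in proximal colon (horizontal axis) and distal colon (vertical axis) for the measured members of 4 gene lists, with equal change on the dotted line. The 29 cell cycle genes lie below 0 distally (26 called lower) with no called change proximally, while 13 and 11 of 19 macrophage genes rose in distal and proximal colon; values of genes near 0 counts depend on the prior count.

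From day 1 to day 7, 11 of 22 colonocyte genes rose in proximal colon and none fell (14 over the list alone), with camera adjusted p = 1.59e-08, adjusted p = 0.0661 with an estimated correlation. Car1, a carbonic anhydrase of the colonocyte, rose from 33.9 ± 5.79 to 229 ± 3.20 FPKM (difference in log2(FPKM + 1) 2.73 ± 0.15, adjusted p = 1.61e-05) and the sodium/hydrogen exchanger Slc9a3 from 1.91 ± 0.325 to 8.77 ± 1.17 FPKM (adjusted p = 7.98e-05). Pigr, which carries antibodies into the lumen, rose from 37.8 ± 6.53 to 144 ± 15.9 FPKM (adjusted p = 9.13e-05). Afp fell from 62.1 ± 22.1 to 6.57 ± 2.98 FPKM (adjusted p = 7.70e-04), the imprinted RNA H19 from 667 ± 237 to 154 ± 10.8 FPKM (adjusted p = 9.87e-04) and the esterase gene Ces1c from 41.0 ± 2.79 to 6.88 ± 1.05 FPKM (adjusted p = 1.23e-05).

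Among bile acid genes the binding protein Fabp6 fell from 12.9 ± 7.65 to 0.568 ± 0.111 FPKM (-2.94 ± 0.40, adjusted p = 0.00282). Vdr rose from 6.92 ± 2.05 to 20.1 ± 1.73 FPKM (1.44 ± 0.16, adjusted p = 0.00114), Abcc3 from 4.70 ± 1.69 to 13.1 ± 1.69 FPKM (1.34 ± 0.19, adjusted p = 0.00310) and Nr1i2, the xenobiotic and bile acid receptor PXR, from 16.2 ± 2.46 to 25.1 ± 0.909 FPKM (adjusted p = 0.0114, and 0.0549 without day 7 library 3). Slc10a2 was at 14.0 ± 2.21 against 12.9 ± 6.08 FPKM (adjusted p = 0.672), Slc51a at 54.4 ± 6.04 against 51.6 ± 7.67 FPKM (adjusted p = 0.775) and Slc51b at 20.02 ± 1.30 against 21.5 ± 5.11 FPKM (adjusted p = 0.861). Nr1h4 was at 42.8 ± 6.36 against 42.6 ± 6.31 FPKM (adjusted p = 0.976), Cyp27a1 at 6.55 ± 0.313 against 6.06 ± 2.02 FPKM (adjusted p = 0.656) and Fgf15 at 1.72 ± 0.329 against 5.94 ± 5.48 FPKM (adjusted p = 0.220). Of 13 transport genes 2 rose and 2 fell (6 and 2 over the list alone; camera adjusted p = 0.224; median 0.18, mean -0.01), and of 12 receptor and target genes 3 rose (4 over the list alone; camera adjusted p = 0.0900). The calls of Slco3a1 (0.44) and Abcc2 (-0.79) ended whichever of the 6 libraries was left out, and that of Nr1h3 (0.42) without any 1 library except day 1 library 3 (adjusted p up to 0.167, 0.148 and 0.128). Cyp7a1 was listed at 0 in all 9 libraries, and Gpbar1 stayed under the expression filter (0.664 ± 0.117 FPKM at day 1, 0.147 ± 0.0300 at day 21).

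Members of further lists were called in the same interval. Of 6 measured MHC class II genes 4 rose (5 over the list alone), with adjusted p = 0.286 with an estimated correlation. Cd74 (27.6 ± 8.03 against 6.66 ± 1.68 FPKM, adjusted p = 8.71e-04) was among them. Of 20 antimicrobial genes 7 rose (12 over the list alone), with adjusted p = 0.286 with an estimated correlation. Among them was Dmbt1 (461 ± 24.5 against 212 ± 41.2 FPKM, adjusted p = 0.00235). Of 28 conjugation and detoxification genes 12 rose and 1 fell (15 and 4 over the list alone), with adjusted p = 0.286 with an estimated correlation. These included the carboxylesterase Ces2e (77.4 ± 9.52 against 28.3 ± 4.02 FPKM, adjusted p = 3.67e-04). Of 18 suckling-type enterocyte genes 6 fell (7 over the list alone), with adjusted p = 0.294 with an estimated correlation. The lysosomal enzymes Gusb (-0.62 ± 0.08, adjusted p = 0.00187) and Glb1 (-0.68 ± 0.11, adjusted p = 0.00723) were among them. The calls of Mttp and Cps1 ended without day 7 library 2 or 3 (adjusted p up to 0.0997 and 0.101). Of 12 enteroendocrine genes 1 rose and 4 fell (1 and 5 over the list alone), with adjusted p = 0.294 with an estimated correlation. Pyy fell (-0.66 ± 0.08, adjusted p = 0.00188). Of the other 3 falls, that of Insl5 ended without day 7 library 1 or 2, that of Sct without day 1 library 1 or day 7 library 2 or 3, and that of Gcg without any 1 library except day 1 library 3 (adjusted p up to 0.0511, 0.110 and 0.133). Of 7 measured hepatocyte genes 5 fell (5 and 1 higher over the list alone), such as Ttr (19.4 ± 1.69 against 48.0 ± 4.45 FPKM, adjusted p = 3.13e-04; adjusted p = 0.294 with an estimated correlation). Alb, the liver transcript, was at 31.1 FPKM in day 1 library 1 and at most 2.12 FPKM in the other 8. Of 29 cell cycle genes 4 fell (11 over the list alone; adjusted p = 0.421 with an estimated correlation). Bub1 had the smallest p (-0.61 ± 0.13). None of these 4 calls outlasted leaving out any day 7 library (adjusted p up to 0.0913 for Bub1). Other large rises were those of Calb2 (3.09 ± 0.16), Mt2 (3.08 ± 0.50), Apol10a (2.20 ± 0.20), Cmah (1.87 ± 0.28) and the disaccharidase Sis (2.18 ± 0.15). Hnrnpa3 (-2.89 ± 0.16) and mt-Tk (-2.15 ± 0.22) fell.

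In all, 620 genes rose and 373 fell between day 1 and day 7. That number moved with single libraries: 465, 373 and 382 genes were called without day 7 library 1, 2 or 3, and 1625 without day 1 library 3. No list of this comparison was called with an estimated correlation, against 19 at the preset one.

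Between day 7 and day 21 genes of bile acid transport rose in proximal colon. Slc10a2 rose from 14.0 ± 2.21 to 63.5 ± 5.80 FPKM (2.11 ± 0.25, adjusted p = 8.25e-05), Slc51b from 20.02 ± 1.30 to 66.4 ± 21.6 FPKM (1.63 ± 0.23, adjusted p = 2.43e-04) and Abcc3 from 13.1 ± 1.69 to 62.9 ± 4.92 FPKM (2.18 ± 0.19, adjusted p = 1.22e-05). The drug efflux pump Abcb1a rose from 25.9 ± 1.70 to 149 ± 23.6 FPKM (adjusted p = 2.40e-06). Fabp6, which had fallen by day 7, rose from 0.568 ± 0.111 to 17.1 ± 4.00 FPKM (3.50 ± 0.40, adjusted p = 6.74e-05), and at day 21 did not differ detectably from day 1 (difference 0.56 ± 0.40, adjusted p = 0.253). Of 13 transport genes 8 rose and 1 fell, as over the list alone (camera adjusted p = 5.95e-05, adjusted p = 0.0400 with an estimated correlation). Slc51a rose from 54.4 ± 6.04 to 80.3 ± 15.4 FPKM (adjusted p = 0.0145), a call that ended without day 7 library 3, without day 21 library 3 and with quantile scaling (adjusted p up to 0.0683). The receptors Nr1h4 (84.6 ± 10.4 against 42.8 ± 6.36 FPKM, adjusted p = 4.40e-04), Vdr (71.7 ± 7.91 against 20.1 ± 1.73 FPKM, adjusted p = 1.85e-05) and Nr1i2 (34.5 ± 1.55 against 25.1 ± 0.909 FPKM, adjusted p = 0.00722) rose, with 6 of 12 receptor and target genes higher and 2 lower, as over the list alone (camera adjusted p = 0.00287, adjusted p = 0.10 with an estimated correlation). Cyp27a1 was at 8.73 ± 0.496 against 6.55 ± 0.313 FPKM (adjusted p = 0.128) and Fgf15 at 0.828 ± 0.447 against 1.72 ± 0.329 FPKM (adjusted p = 0.340).

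**Figure D3:**
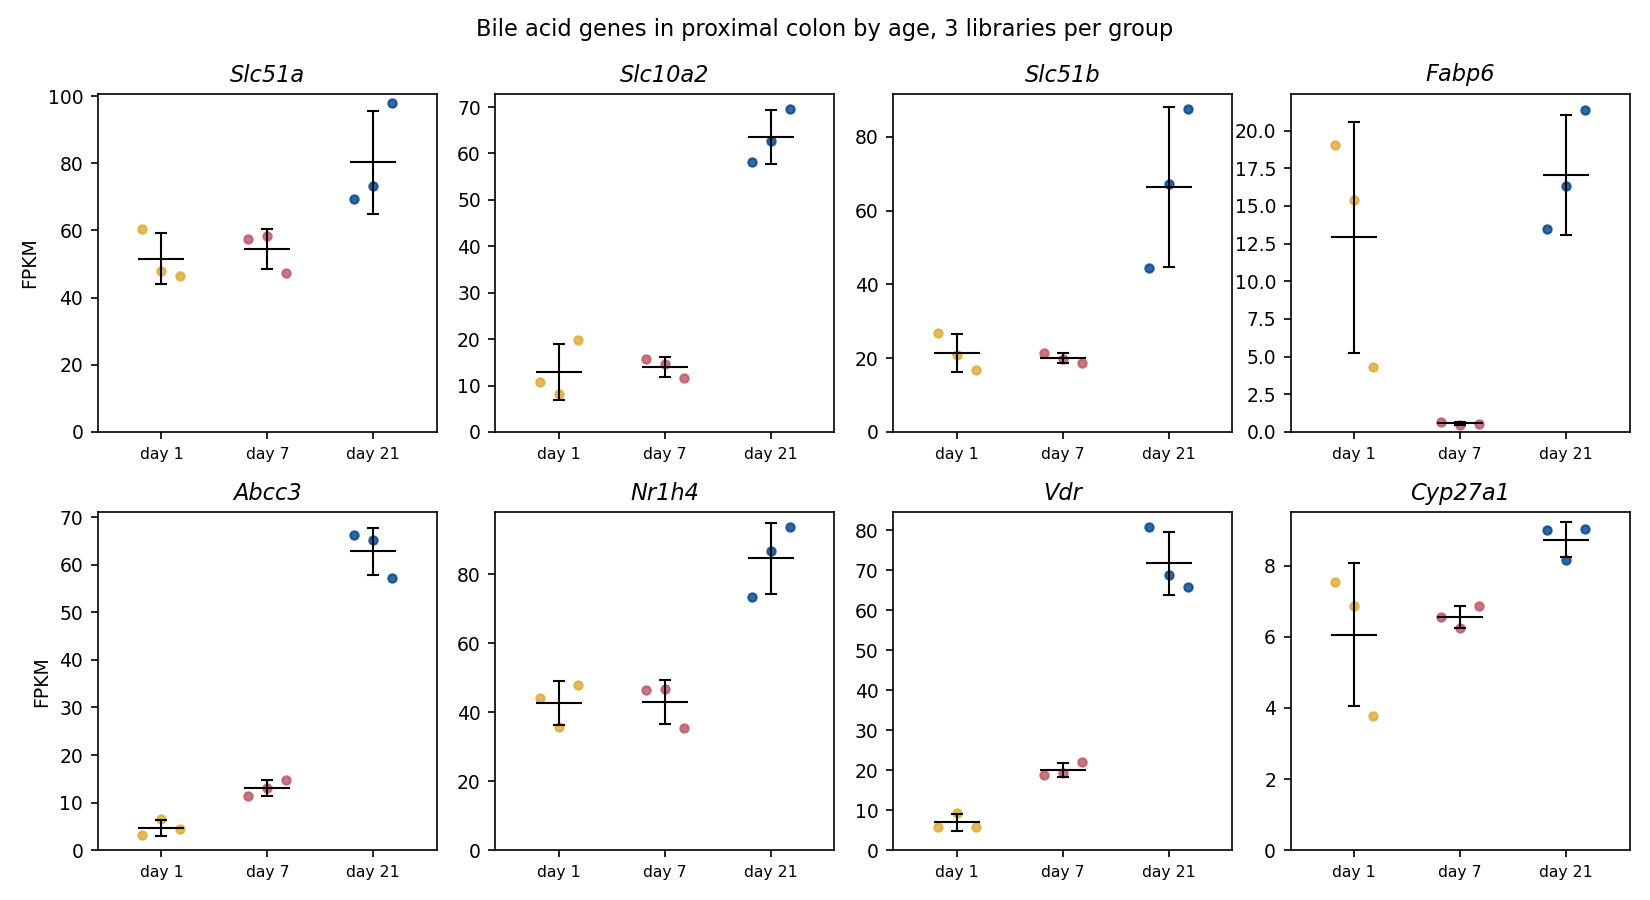
FPKM of 8 bile acid genes in proximal colon by age: points are the 3 libraries of a group, the horizontal mark their mean and the bars the SD, on linear axes from 0. Slc10a2 was at 12.9, 14.0 and 63.5 FPKM on day 1, day 7 and day 21, Abcc3 at 4.70, 13.1 and 62.9 FPKM, and Fabp6 at 12.9, 0.568 and 17.1 FPKM.

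Colonocyte genes rose in the same interval. Car1 rose from 229 ± 3.20 to 5499 ± 888 FPKM (4.57 ± 0.15, adjusted p = 1.28e-07), Car4 from 3.53 ± 1.10 to 61.4 ± 6.40 FPKM (adjusted p = 4.27e-07) and the keratin Krt20 from 68.3 ± 0.664 to 496 ± 114 FPKM (adjusted p = 1.30e-06), with 16 of 22 colonocyte genes higher and 3 lower (17 and 3 over the list alone; camera adjusted p = 1.23e-11, adjusted p = 0.0272 with an estimated correlation). Of 28 conjugation and detoxification genes 24 rose, as over the list alone, with camera adjusted p = 2.95e-18, adjusted p = 0.0272 with an estimated correlation. Cyp2c55 (979 ± 145 against 83.5 ± 4.21 FPKM, adjusted p = 1.65e-06) and Ces2a (34.5 ± 5.44 against 1.26 ± 0.192 FPKM, adjusted p = 3.90e-07) were among them. Of 15 weaning-associated genes 12 rose, as over the list alone, with camera adjusted p = 2.27e-09, adjusted p = 0.0283 with an estimated correlation. Among them were Reg3g (116 ± 27.3 against 2.10 ± 0.445 FPKM, adjusted p = 4.27e-07) and Retnlb, a goblet cell effector induced by microbes (79.6 ± 26.9 against 3.11 ± 0.630 FPKM, adjusted p = 1.58e-06). Of 29 interferon response genes 27 rose, as over the list alone, with adjusted p = 0.121 with an estimated correlation. These included Oas3 (10.6 ± 2.60 against 0.327 ± 0.165 FPKM, adjusted p = 9.23e-07) and Irf7 (57.5 ± 7.09 against 9.22 ± 2.13 FPKM, adjusted p = 4.49e-06). Of 6 plasma cell genes 4 rose and 1 fell, as over the list alone, with adjusted p = 0.138 with an estimated correlation. Igha, the heavy chain of the gut antibody, rose (10.4 ± 4.00 against 0.151 ± 0.0332 FPKM, adjusted p = 2.95e-06). Of 17 tight junction genes 13 rose and 1 fell (14 and 1 over the list alone), with adjusted p = 0.10 with an estimated correlation. Cldn3 rose (208 ± 9.24 against 68.8 ± 3.32 FPKM, adjusted p = 1.22e-05) and Cldn8 fell (-1.13 ± 0.15, adjusted p = 2.23e-04). Of 27 nuclear OXPHOS genes 15 rose, as over the list alone, such as Cycs (0.95 ± 0.13, adjusted p = 2.17e-04; adjusted p = 0.138 with an estimated correlation). Under TMM-type scaling 24 rose and under quantile scaling 5.

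Genes of further lists fell or went both ways. Of 13 enteric neuron and glia genes 10 fell and 1 rose, as over the list alone, with adjusted p = 0.149 with an estimated correlation. These included the receptor Ret (3.18 ± 0.446 against 16.4 ± 0.528 FPKM, adjusted p = 5.88e-07). Of 29 cell cycle genes 20 fell (24 over the list alone), with adjusted p = 0.486 with an estimated correlation. Foxm1 (-0.87 ± 0.09, adjusted p = 4.59e-05) was among them. Of 18 suckling-type enterocyte genes 11 fell and 1 rose, as over the list alone, with adjusted p = 0.233 with an estimated correlation. Among them was the endocytic adaptor Dab2 (-1.87 ± 0.17, adjusted p = 1.56e-05). Of 20 patterning factors 9 rose and 7 fell, as over the list alone, with Hoxb6 up (1.69 ± 0.17, adjusted p = 3.48e-05) and Hoxa13 down (-1.81 ± 0.19, adjusted p = 4.08e-05; adjusted p = 0.217 with an estimated correlation). The largest other rises were those of Clca4a (4.59 ± 0.22), Ifit1bl1 (4.04 ± 0.38), Sptssb (3.94 ± 0.19) and Plet1 (3.93 ± 0.18). The largest falls were those of Mamdc4 (-3.49 ± 0.25), the imprinted gene Mest (-3.16 ± 0.13), Atp12a (-3.12 ± 0.38), Serpina1b (-3.08 ± 0.24), Itm2a (-2.95 ± 0.16), Gatm (-2.93 ± 0.15) and Emilin3 (-2.74 ± 0.12), with adjusted p of at most 9.98e-05 (limma). In all, 2028 genes rose and 5214 fell. This split rests on the scaling: the median log2 difference of all genes was -0.17 with the FPKM as deposited, and with TMM-type scaling, where it was -0.01, 3292 genes rose and 3482 fell (2836 and 3228 with quantile scaling).

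**Figure D4:**
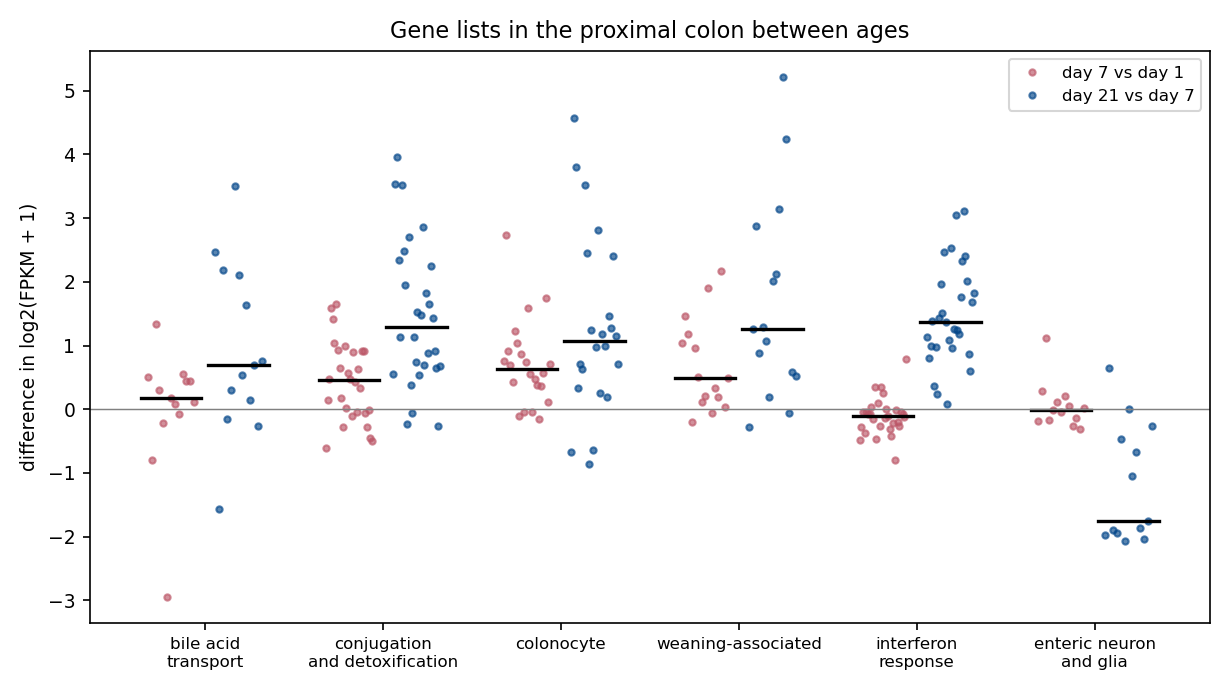
Difference in log2(FPKM + 1) of the measured members of 6 gene lists in proximal colon, day 7 minus day 1 and day 21 minus day 7: points are genes and the black line is their median. For day 21 against day 7 the lists of bile acid transport (8 of 13 called higher), detoxification (24 of 28), colonocyte (16 of 22), weaning (12 of 15) and interferon (27 of 29) lie mostly above 0 and enteric neurons (10 of 13 called lower) mostly below.

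Over the whole span from day 1 to day 21, Vdr rose from 6.92 ± 2.05 to 71.7 ± 7.91 FPKM (3.22 ± 0.16, adjusted p = 2.87e-07), Abcc3 by 3.52 ± 0.19 (adjusted p = 3.65e-07) and Slc10a2 by 2.29 ± 0.25 (adjusted p = 3.19e-05). Slc51b rose by 1.56 ± 0.23 (adjusted p = 2.26e-04), Nr1i2 by 1.06 ± 0.11 (adjusted p = 2.56e-05), Nr1h4 by 0.98 ± 0.15 (adjusted p = 2.98e-04) and Slc51a by 0.62 ± 0.15 (adjusted p = 0.00568). The export pump Abcc2 fell from 16.4 ± 2.34 to 2.45 ± 0.860 FPKM (-2.35 ± 0.20, adjusted p = 5.66e-06). Of 13 transport genes 8 rose and 1 fell, as over the list alone (camera adjusted p = 1.07e-04, adjusted p = 0.0475 with an estimated correlation), and of 12 receptor and target genes 8 rose and 3 fell, as over the list alone (camera adjusted p = 0.00221, adjusted p = 0.0856 with an estimated correlation). Fgf15 fell (0.828 ± 0.447 against 5.94 ± 5.48 FPKM, adjusted p = 0.0170) and Cyp27a1 rose (8.73 ± 0.496 against 6.06 ± 2.02 FPKM, adjusted p = 0.0369). The first call ended without day 21 library 1 or 2 and the second without any day 21 library (adjusted p up to 0.0663 and 0.0983). Of 12 synthesis genes 7 rose and 3 fell, as over the list alone, with Hsd17b4 up (0.73 ± 0.10, adjusted p = 1.43e-04) and the brain-type cholesterol hydroxylase Cyp46a1 down (-1.44 ± 0.14, adjusted p = 1.45e-05; camera adjusted p = 0.0847).

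Colonocyte and detoxification genes rose over the whole span too. Of 22 colonocyte genes 17 rose, as over the list alone, Car1 by 7.30 ± 0.15 (adjusted p = 3.39e-09) and Slc9a3 by 4.15 ± 0.12 (adjusted p = 2.01e-08), with camera adjusted p = 6.72e-13, adjusted p = 0.0283 with an estimated correlation. Of 28 conjugation and detoxification genes 24 rose and 1 fell, as over the list alone, with camera adjusted p = 7.53e-15, adjusted p = 0.0294 with an estimated correlation. These included Ces1g (12.3 ± 0.556 against 0.0319 ± 0.0313 FPKM, adjusted p = 8.87e-09) and Papss2, which makes the sulfate donor (156 ± 7.28 against 29.3 ± 3.71 FPKM, adjusted p = 1.03e-07). All 6 measured MHC class II genes rose, as over the list alone, H2-Ab1 from 2.02 ± 0.447 to 17.7 ± 1.70 FPKM (adjusted p = 4.90e-07; adjusted p = 0.143 with an estimated correlation). Of 12 immediate early and heat shock genes 10 rose, as over the list alone, with adjusted p = 0.143 with an estimated correlation. Fos (32.6 ± 3.52 against 3.68 ± 2.55 FPKM, adjusted p = 6.82e-05) was among them. Of 25 cholesterol synthesis genes 14 fell and 1 rose, as over the list alone, such as Insig1 (-1.18 ± 0.18, adjusted p = 2.75e-04). Camera did not call the list (adjusted p = 0.228), and under TMM-type scaling 8 fell. The imprinted growth genes H19 (36.1 ± 6.30 against 667 ± 237 FPKM, adjusted p = 4.17e-07), Igf2 (-4.06 ± 0.22, adjusted p = 4.18e-07) and Mest (-4.22 ± 0.13, adjusted p = 2.37e-08) fell, as did Mir675, which lies inside H19 (-3.71 ± 0.26, adjusted p = 1.79e-06), Ces1c (-4.93 ± 0.11), Serpina1b (-4.51 ± 0.24), Mamdc4 (-4.14 ± 0.25) and Meltf (-3.70 ± 0.30). The largest other rises were those of Apol10a (5.88 ± 0.20), Clca4a (5.28 ± 0.22), Sectm1b (4.86 ± 0.21) and Plet1 (4.53 ± 0.18). In all, 2888 genes rose and 5833 fell, against 3935 and 4286 with TMM-type and 3568 and 4231 with quantile scaling.

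The libraries of the age series also differed in sex-linked transcripts. Xist, made from the inactive X chromosome, lay between 15.8 and 71.6 FPKM in all 9 libraries, and 8 of them also held more than 1 FPKM of the Y-linked genes Ddx3y and Eif2s3y. Whether each library came from 1 animal or from a pool of both sexes is not given in the sources used here, so the n = 3 and the SD of a group could be those of pools. Day 7 library 1 had 71.6 FPKM of Xist, 0.218 of Ddx3y and 0.388 of Eif2s3y. In the DSS experiment Xist was at most 0.442 CPM and Ddx3y at least 56.5 CPM in every library. Of the 5 sex-linked genes none was called between DSS and water in either colon part (none over the list alone), and 1 was called lower at day 21 than at day 7. None was called between day 1 and day 7, where 3 were lower over the list alone.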

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

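Of the tests below, those on epithelial markers, on the position along the colon, on S100a8 and S100a9 and on relatives of Ly6g were chosen after the result they address had been seen. Each pattern is therefore a hypothesis on the same data.

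In distal colon 26 of 29 cell cycle genes, such as Mki67 and Mcm5, fell with DSS. Lower depth of the DSS distal libraries was argued against: with every library thinned to the lowest total (54.2 M counts), 1934 genes were called, and 26 cell cycle genes were lower as before. No single library carried the pattern, since at least 25 of these genes were called lower with any 1 of the 10 distal libraries left out. A smaller share of epithelium was also argued against. The 15 epithelial marker genes had a median log2 change of 0.19 (quartiles 0.03 to 0.41), against -1.27 for the cell cycle genes (upper quartile -0.94). Fewer dividing crypt cells, or less expression in each, may explain the fall, and these were not separated here.

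Slc10a2 and Isx, both far higher in proximal colon, rose in distal colon with DSS. Proximal tissue in the DSS distal samples was argued against: 26 genes at least 100 times higher proximally gained a median of 0.0141% of their proximal level (quartiles -0.0455 to 0.0726), against 5.89% for Slc10a2. Distal samples taken further up the colon cannot be told apart from an effect of DSS, since how steeply each gene changes along the colon was not measured. The 550 genes at least 4 times higher proximally had a median log2 change of 0.17 (quartiles -0.27 to 0.81, 47 called higher and 33 lower), against 1.64 for Slc10a2, the 520 as much higher distally had -0.03 (-0.59 to 0.37), and of 24 patterning factors Isx alone rose and 2 fell. No shift of all such genes as large as that of Slc10a2 was thus seen, but a smaller shift in position or a change in the epithelium with DSS could each raise these 2 genes.

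Ly6g was at 0.0274 CPM in control proximal colon and reached up to 15.6 CPM with DSS. Neutrophils as its source were argued against: the higher of S100a8 and S100a9, abundant neutrophil transcripts, came to at most 0.283 of the Ly6g gained in any DSS proximal library, with highest values of 2.44 and 4.33 CPM. Distal tissue in the proximal samples was argued against too. The 23 genes at least 100 times higher distally gained a median of 0% of their distal level (upper quartile 0.329), against 5.31% for Ly6g. Reads of 7 measured Ly6 relatives were argued against, since their highest fold was 3.23, for Ly6a (75.5 to 244 CPM) and the low Ly6i; relatives under the filter were not tested. Expression of Ly6g in another cell type may remain as a candidate explanation and was not tested.

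The DSS effect differed between the colon parts for 726 genes by the interaction test. In log2 units, distal minus proximal, the differences toward distal were 2.74 for Isx, 2.53 for Krt84, 2.13 for Gal3st2c, 2.02 for Slc37a2, 1.96 for Actc1, 1.87 for Slc10a2, 1.02 for Gcg, 0.97 for Pyy, 0.70 for Cyp27a1 and 0.63 for Abcc3. Toward proximal they were -5.31 for Mmp10, -4.42 for Lgr5, -3.67 for Il11, -2.16 for Cdca7, -1.80 for Mcm5, -1.79 for Aurkb and -1.52 for Bank1. Smaller ones were -1.05 for Cftr, -0.79 for Il1rn and -0.73 for Slc12a2. For Acod1 (-8.57), Ly6g (-8.07), Il6 (-7.79) and Ascl2 (-6.42) a group lies near 0 counts, so these fitted values depend on the prior count. With 1 library left out, the call of Slc37a2 ended in 16 of 20 fits and that of Il6 in 12 of 20 (adjusted p up to 0.0938 and 0.258), and Il6 was not called with DESeq2 either (0.113).

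In 19 of 168 groups of 5 values 1 library lay far from the other 4. Chance gives 8.4 for values without ties, which does not hold near 0: for Abca12, Reg3b, Casp14, Ces1b and Il6 in proximal colon the other 4 libraries had no count, so any count stands apart. In control distal colon these were Vdr (249 CPM, library 1), Gal3st2c (37.7, library 1), Il6 (0.866, library 2), Abca12 (0.0614, library 3), Reg3b (0.0305, library 4) and Cd207 (2.77, library 5). In control proximal colon they were Actc1 (5.09 CPM, library 1), Nr1h4 (218, library 2), Serpina3m (0.671, library 2), Casp14 (0.0652, library 4) and Il6 (0.0878, library 5). In DSS distal colon they were Pcdhgb1 (3.32 CPM, library 1), BB123696 (1.63, library 2), Cyp27a1 (89.4, library 2), Krt84 (8.62, library 4), Ces1b (0.162, library 5) and Slc51a (0.307, library 5). In DSS proximal colon they were Cyp2w1 (1.04 CPM, library 1) and Fabp6 (16.1, library 5, with 2.32 as the nearest other value).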

How the results depend on the processing

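All alternatives here were chosen before the values were seen. Of 500 values of named genes 450 passed the threshold, and 395 of these passed it under every alternative other than the minimum change. The other 55 fell short under at least 1, and none changed direction. Of the 50 that did not pass, 17 passed under some alternative and 8 changed sign.

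With a log2 change of at least 1 required, 505 genes were called for DSS in distal colon, 265 in proximal colon, 311 for the interaction, 2385 and 2559 for proximal against distal colon with water and with DSS, 156 for day 7 against day 1, 1385 for day 21 against day 7 and 2060 for day 21 against day 1. This asks for more by construction. With DESeq2 the interaction gave 1313 genes, 44.3% higher distally against 31.0% with edgeR. Its size factors in edgeR gave 731, 39.8% higher.

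For day 7 against day 1 (993 genes) the count was 635 without a filter, 637 with a filter on the mean, 439 with the compared groups fitted alone and 3057 with array weights. For day 21 against day 7 (7242) it was 3821 with the filter on the mean and 11206 with array weights, and for day 21 against day 1 (8721) it was 4846 with the filter on the mean. The causes were not tested. The share of called genes that rose also moved with scaling: for day 21 against day 7 it was 28.0% with the values as deposited, 46.8% with quantile and 48.6% with TMM-type scaling, and for day 21 against day 1 it was 33.1%, 45.7% and 47.9%.

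With 1 library left out, DSS in distal colon gave 1367 to 2201 genes, in proximal colon 623 (without DSS library 1) to 1274 (without DSS library 3), and 740 and 724 without control libraries 4 and 5. The interaction gave 509 to 918, proximal against distal colon 5884 to 6415 with water and 6408 to 7360 with DSS. Day 7 against day 1 gave 373 (without day 7 library 2) to 1625 (without day 1 library 3), with 465 and 382 without day 7 libraries 1 and 3 and 999 without day 1 library 1. Day 21 gave 5624 to 6325 against day 7 and 7380 to 8898 against day 1. Fewer libraries are tested in each.

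Camera at an estimated correlation called fewer lists than at the preset one: 3 of 22 for DSS in distal colon, 5 of 15 in proximal colon, 2 of 12 for the interaction, 6 of 17 and 3 of 18 for proximal against distal colon with water and with DSS, 0 of 19 for day 7 against day 1, 4 of 27 for day 21 against day 7 and 4 of 26 for day 21 against day 1. This test allows for genes of a list moving together.

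The replicate number as a block gave 1937, 1130, 724, 6581 and 7372 genes in the DSS experiment and 688, 6835 and 8366 in the age series, in the order above. For 1937, 1130 and the age counts the block joins different animals, so tests no pairing. The 10 pairs with the same number correlated at 0.0203 to 0.207 after removing group means (3 above 0.1), and 7 of 10 distal libraries matched their own number best. The block was not used, since its criterion, above 0.1 in every pair, failed. All 10 were above 0, so with the 7 best matches a link by number, perhaps shared animals, stays open. In the interaction Il6, Slc37a2, Acod1 and Cxcl5 were not called with the block (adjusted p = 0.108, 0.0620 and 0.0841 for the last 3).

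Genes without a call changed sign in places, on the log2 scale. For DSS in proximal colon, leaving out 1 library gave -0.44 to 0.058 for Gpbar1 (0.058 without control library 5) and -0.025 to 0.16 for Slc51b (-0.021 and -0.025 without control libraries 3 and 5). For Cyp27a1 in proximal against distal colon with water it gave -0.092 to 0.035, with 0.035 without control distal library 2 and 0.013 and 0.0083 without control proximal libraries 1 and 4. With DESeq2 size factors and with DESeq2 it was 0.0014. For day 7 against day 1, Nr1h4 ran from -0.11 (without day 1 library 2) to 0.14, with -0.054 and -0.056 without day 7 libraries 1 and 2 and -0.0019 with TMM-type scaling. Slc10a2 ran from -0.074 (without day 1 library 2) to 0.51, Slc51b from -0.23 to 0.10 (without day 1 library 1) and Cyp27a1 from -0.12 (without day 1 library 3) to 0.30. For day 21 against day 1, Fabp6 ran from -0.028 (without day 1 library 3) to 0.93. The causes were not tested.

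Depth limits the DSS experiment at about 3 counts per library, and for the age series it is unknown.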

Other observations

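No test in this part was chosen after its result was seen, apart from the choice of which further lists to mention. With DSS in distal colon 3 of 13 endothelial genes rose (6 adjusted over the list alone, camera adjusted p = 0.176 with an estimated correlation) and 2 of 12 plasma cell genes fell (3 adjusted over the list alone, adjusted p = 0.339). In proximal colon with DSS 2 of 14 tuft cell genes rose (adjusted p = 0.190), and no member of the 10 MHC class II genes was called. Between day 7 and day 21, 14 of 20 antimicrobial genes rose and 1 fell (adjusted p = 0.124), and 14 of 18 fibroblast and matrix genes fell (adjusted p = 0.292). From day 1 to day 21, 26 of 29 interferon response genes rose (adjusted p = 0.143), and 25 of 29 cell cycle genes fell (adjusted p = 0.364). These p-values are from camera with an estimated correlation.

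A hypothesis was that with DSS the colon moves toward the expression of the younger colon. It predicts a fall of the genes higher at day 21 than at day 7 and a rise of those lower. Of 481 and 904 such genes (proximal colon, log2 difference of at least 1), 464 and 876 were measured in the DSS experiment. In distal colon the genes higher at day 21 moved up instead, with 91 called higher and 41 lower, a median log2 change of 0.16 and a camera p of 0.0490 with an estimated correlation. The genes lower at day 21 had a median of 0.099, the direction predicted, with 45 called higher and 40 lower and a camera p of 0.473. The first p is unadjusted and counts narrowly against the hypothesis in distal colon. In proximal colon the camera p was 0.748 and 0.442, which leave it undecided.

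The libraries were also split in other ways, with the compared groups fitted alone. DSS against water called 1712 genes in distal colon against at most 9 in 69 other splits, and 774 in proximal colon against at most 1. Proximal against distal colon called 6224 genes with water against at most 328, and 6758 with DSS against at most 1. The interaction called 726 against at most 70. In each, 1 of 70 splits, the real one, gave as many, so chance is unlikely if libraries are independent. In the age series 10 splits of 6 libraries are too few for a share under 0.05. Real and highest other values were 439 and 1 for day 7 against day 1, 8979 and 0 for day 21 against day 7, and 7836 and 0 for day 21 against day 1.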
